A study of Ginkgo biloba with 6 samples.

How the data were processed

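RNA was extracted from leaves of truncated and control Ginkgo biloba trees and sequenced as 6 Illumina libraries, 3 per group. The submitters' processing notes name CASAVA 1.8, TopHat2 and RSEM, with no version for TopHat2 or RSEM and no order or role. CASAVA is Illumina's base calling and demultiplexing software, TopHat2 a spliced aligner and RSEM a program that estimates transcript abundance. The genome build and annotation are not given in the sources used here. The values are FPKM as deposited, per the file headers, with 1 column per library, rounded to 2 decimals. No scaling between libraries beyond FPKM is recorded in the labels or headers, and no per-sample column was left unused (0). FPKM divides by the mapped fragments of each library, so a library in which few genes take a large share of the fragments has lower values for all other genes. Where reads match several gene copies, the estimate for each copy depends on how the authors' program shared them out.

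Groups were taken from the treatment labels and each column from its library title. FPKM values are not counts, so no count model was fitted. Values were transformed to log2(FPKM + 1), which understates the fold change of weakly expressed genes. IDs with a mean of at least 1 FPKM over the 6 libraries were tested (16054 of 26044, leaving out 9990). The main test was limma 3.58.1 in R 4.3.3, with a group term, all 6 libraries and empirical Bayes variances with a mean trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors and 95% intervals are from the same fit. Library measures were compared with exact permutation tests, two-sided, for which 3 against 3 libraries cannot give a p under 0.1. The test, the filter, the 20 gene lists and most alternatives were fixed before the data were examined. The gene lists were defined by gene names and descriptions. Since the IDs come with none, 0 of the lists were computed, and no name was assigned to any ID.

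The rule for named genes was to name the 2 IDs with the largest rise and the 2 with the largest fall among IDs past the adjusted threshold whose groups did not overlap. No ID met it, so the 2 IDs of each direction with the smallest unadjusted p among non-overlapping groups were named instead, a choice made after the data were seen, as were the abundance classes, the counts at an unadjusted p under 0.05 and of non-overlapping groups, and the comparison of library pairs.

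Depth is not recorded. With whole fragments, equal counts of a gene in 2 libraries give FPKM values whose ratio is the inverse ratio of their depths. The most frequent ratio to control A over IDs between 0.3 and 1.5 FPKM in both libraries was therefore taken as the relative depth (Python 3.11.15, numpy 2.4.6). The estimate assumes that the authors' length correction was alike in all libraries, and it gives no absolute number, so no counting interval or detection limit is stated. The limma test and the depth estimate were tested on simulated data with known answers, and the former also on the real table with known changes added to 200 IDs.

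Whether the letters A to C pair libraries across groups was checked from the deviations of each library from its group mean. These correlated at 0.19 for letter A, -0.58 for B and -0.55 for C. The main fit, fixed beforehand, treated the letters as names and not as pairs, so that choice did not rest on this check. The check cannot exclude a pairing, since control B and truncated C, of different letters, deviated alike. No 2 libraries held identical values. Alternatives changed the pseudocount (0.1 and 0.5), the filter (none, 0.1 and 5 FPKM), the scaling between libraries (to an equal sum, by the median of ratios, by quantiles), the variance model, the threshold (0.01) and the libraries included, and a further fit used the letter as a replicate block. Alternatives added after seeing the data were a covariate made from the first component of the within-group residuals, library quality weights, and the exclusion of control B and truncated C together.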

Results

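Leaf transcriptomes were compared between Ginkgo biloba trees whose trunks had been cut back and uncut trees. Ginkgo is a gymnosperm tree whose leaves are harvested for their flavonoids, a class of phenolic plant metabolites. The trees were 5 years old, of the cultivar Fozhi, and grew in a leaf-harvesting nursery at a spacing of 0.6 m. Truncation left a trunk of 85 cm in 30 trees, and another 30 trees served as controls. Leaves of each group at the harvesting stage gave 3 RNA libraries, lettered A, B and C, so that the data hold 3 control and 3 truncated libraries. The labels do not say how many trees contributed to a library or whether the libraries came from different trees, so p-values measure only the spread between these libraries, which may in part be technical.

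The expression table listed 26044 gene IDs in FPKM, fragment counts scaled by transcript length and by the mapped fragments of the library. Of these IDs, 25439 carried Gb numbers and 605 carried XLOC numbers. Every listed ID was above 0 in at least 1 library, and 18956 were above 0 in all 6. The summed FPKM was between 655395 in truncated C and 738322 in truncated B. The number of sequenced fragments was not given, but the spacing of low FPKM values gave the depth of each library relative to control A. That relative depth was 0.94 in control B, 0.947 in control C, 1.01 in truncated A, 0.933 in truncated B and 1.09 in truncated C. The IDs were paired with no gene names, descriptions or positions in the material used here. The 20 lists of pathway and cell type genes, flavonoid biosynthesis among them, were therefore not tested, and genes are described by ID and by abundance class.

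The series title puts the question as whether rejuvenation by truncation improves flavonoid accumulation, and the one comparison in the design sets truncated leaves against control leaves. No gene passed the main test for a difference between the groups, though 1 alternative fit called genes. Of 16054 gene IDs with a mean of at least 1 FPKM, 0 were higher and 0 were lower in truncated leaves by limma at an adjusted p under 0.05, and the smallest Benjamini-Hochberg adjusted p from limma was 0.385. At an unadjusted p under 0.05, 1103 IDs differed, 690 of them higher and 413 lower in truncated leaves, where 803 would be expected by chance alone. This is no evidence of a treatment effect, since 4 of the 10 splits of the libraries into 3 and 3, the real one included, gave at least 1103. The highest split gave 2271. The excess of higher IDs depended on the fit and on single libraries: the share higher in truncated leaves, 62.6% here, was 45.4% with the first component of the residuals within groups as a covariate (the residual component, added after the data were seen) and 53.0% without truncated A or without truncated C. Without control A, this count was 659 of 16140 tested, and with the residual component it was 2878. With library quality weights, also added after the data were seen, limma called 1853 genes at an adjusted p under 0.05, 1098 higher and 755 lower in truncated leaves, and 4708 at an unadjusted p under 0.05. The estimation of these weights stopped before converging and gave truncated A a weight of 45.0 against at most 2.02 for any other library, and 3 of the 10 splits of the libraries into 3 and 3, the real one included, gave at least 1853 genes, with 4056 the highest. Of the 1103 IDs of the main test, 243 were at least 2-fold higher and 78 at least 2-fold lower in truncated leaves on the log2(FPKM + 1) scale. All 3 truncated values lay above all 3 control values for 1156 IDs and below them for 1107 IDs, together 14.1% of those tested, against the 10% that chance gives for 3 against 3. Of the 10 splits of the libraries into 3 and 3, 4 gave at least as many such IDs as the real one, and the highest gave 3124. With 1 library left out, where chance gives 20%, the share was 32.8% (5171 of 15769) without truncated C and 19.6% to 22.6% without any other library. On the first principal component of all 6 libraries, described below, truncated A and truncated B scored -18.5 and -61.3, and no control scored below -14.7. Without truncated C the groups thus line up with that component, so the higher share cannot be read as an effect of the treatment.

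The 4 IDs with the smallest unadjusted p among non-overlapping groups, 2 in each direction, were chosen after their values were seen, because no ID met the rule fixed beforehand. Gb_23977 averaged 0.957 ± 0.618 FPKM (SD, n = 3) in control leaves and 7.66 ± 1.55 FPKM (SD, n = 3) in truncated leaves, a log2 fold change of 2.17 ± 0.28 (SE). Fold changes here are on the log2(FPKM + 1) scale, which understates those of weakly expressed IDs. With a pseudocount of 0.1 the log2 fold change of Gb_23977 was 3.01. Gb_30904, an abundant transcript, averaged 47.0 ± 14.8 FPKM in control leaves and 147.1 ± 15.9 FPKM in truncated leaves (SD, n = 3), a log2 fold change of 1.66 ± 0.23 (SE). In the opposite direction, Gb_02337 averaged 9.99 ± 0.73 FPKM in control leaves and 3.57 ± 0.97 FPKM in truncated leaves (SD, n = 3), with a log2 fold change of -1.29 ± 0.22 (SE). Gb_07108 averaged 166.4 ± 49.2 FPKM in control leaves and 52.6 ± 14.6 FPKM in truncated leaves (SD, n = 3), with a log2 fold change of -1.64 ± 0.27 (SE). The limma adjusted p was 0.385 for each of Gb_23977, Gb_30904, Gb_02337 and Gb_07108, so that none of the 4 differences passed correction over the 16054 IDs. That in each the 3 truncated libraries lay on one side of the 3 controls was a condition of the choice and no further evidence.

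**Figure D1:**
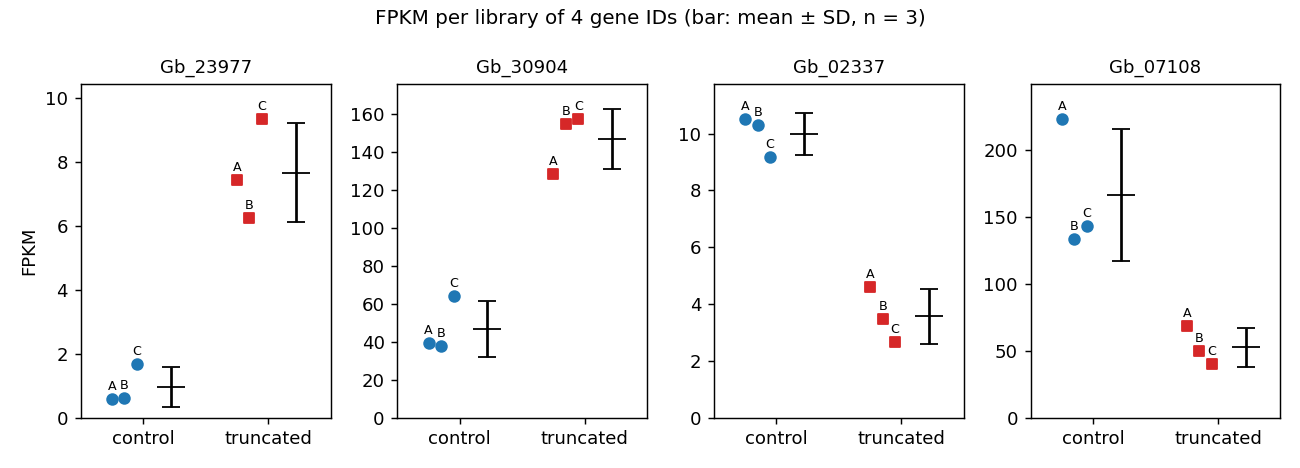
FPKM (y axis, linear from 0, a separate scale per panel) of Gb_23977, Gb_30904, Gb_02337 and Gb_07108 in the control and truncated libraries A to C, with the mean ± SD of each group (n = 3) as a bar. The groups do not overlap in any panel, as the choice of these IDs required. Gb_23977 averages 0.957 FPKM in control and 7.66 FPKM in truncated leaves, and Gb_07108 averages 166.4 and 52.6 FPKM.

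Gene IDs were then grouped by abundance. Among 6444 weakly expressed IDs, with a mean of 1 to 5 FPKM, 322 were higher and 133 lower in truncated leaves at the unadjusted level. Among 7786 IDs of 5 to 50 FPKM, 299 were higher and 222 lower. Among 1824 IDs of at least 50 FPKM, 69 were higher and 58 lower. The share of IDs at this level was 7.06%, 6.69% and 6.96% in the 3 classes, and no member of any class passed the adjusted threshold in limma. The 100 most abundant IDs held 2 at the unadjusted level, both higher in truncated leaves, where 5 would be expected by chance. The 266 tested XLOC loci held 11 higher and 10 lower. Of the most abundant transcripts, 1 pair of IDs with a mean of 13887 FPKM had identical values in every library, and 93 tested IDs shared all 6 values with another ID, so that the levels of such copies are uncertain.

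The absence of calls was read against the precision of the data. The median standard error of a log2 fold change was 0.25. For 10289 of the 16054 IDs, 64.1%, the unadjusted 95% interval excluded a 2-fold change in either direction on the log2(FPKM + 1) scale. As this scale understates changes of weakly expressed IDs, such an interval need not exclude a 2-fold change in FPKM for them. Of the IDs tested, 6444 had a mean of 1 to 5 FPKM. The truncated values of 200 randomly chosen IDs were multiplied or divided by known factors in the real table, all in the same fit. The same limma test recovered 6 of 50 changes of 2-fold and 21 of 50 of 4-fold. It recovered 35 of 50 of 8-fold and 42 of 50 of 16-fold. It also called 4 of the other IDs, which kept their real values, so these calls are not known to be false. Calls on the larger changes loosen the adjusted threshold for the smaller ones. In a simulation of independent draws the test recovered 13, 34, 43 and 49 of 50, with 11 false calls. There the full change was added on the log2(FPKM + 1) scale, on which the same factor applied to FPKM gives a smaller change. The counts from the draws and from the real table therefore cannot be compared fold for fold. Added changes of 2-fold thus mostly failed the adjusted threshold with these libraries. The spread between libraries was larger in truncated leaves, with a median SD of 0.34 on the log2(FPKM + 1) scale, than in control leaves, with a median SD of 0.23. The difference between these SDs was not tested.

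Similarity between libraries of the same group and of different groups overlapped. Over the tested IDs, Pearson's r of log2(FPKM + 1) was 0.948 to 0.985 among the 3 pairs of control libraries, 0.887 to 0.965 among the 3 pairs of truncated libraries and 0.886 to 0.984 among the 9 pairs across groups. Control A and control C differed by at least 2-fold in 263 IDs, and control C and truncated A in 244. Truncated B and truncated C, of the same group, differed by at least 2-fold in 4138 IDs. Control B and truncated C differed in 1072 IDs, fewer than separated control B from control A (1666) or truncated C from truncated A (2071).

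A principal component analysis of the same values gave a first component with 59.0% of the variance. It set control B, at a score of 51.3, and truncated C, at 57.8, against truncated B at -61.3, with the other libraries between -18.5 and -14.6. Its scores did not separate the groups (exact permutation test, two-sided, p = 0.8). The second component, with 20.9% of the variance, placed the 3 control libraries between -29.1 and -18.6 and the 3 truncated libraries between 1.99 and 36.3. This complete separation gave p = 0.1 in the exact permutation test, which is the smallest p that 3 against 3 libraries allow.

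**Figure D2:**
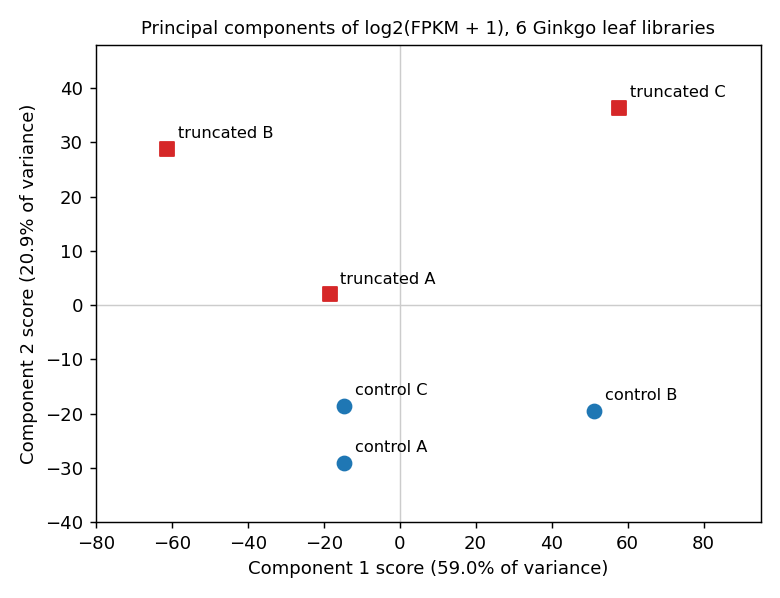
Scores of the 6 libraries on the first 2 principal components of log2(FPKM + 1), with the share of variance on each axis (59.0% and 20.9%); circles are control and squares truncated libraries. Control B and truncated C lie together at the right of component 1, and component 2 places all controls below all truncated libraries.

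The most abundant transcripts took different shares of the transcript pool in different libraries, and this also ran across the groups. The 100 highest IDs held 38.4% of the summed FPKM in control B and 38.2% in truncated C, against 50.7% in truncated B and 43.7% to 45.4% in the other libraries. The group means were 42.5 ± 3.7% in control and 44.2 ± 6.2% in truncated leaves (SD, n = 3), a difference smaller than the spread between libraries (exact permutation test, two-sided, p = 1). The number of IDs at 1 FPKM or more was highest in truncated C (16705) and control B (16218) and lowest in truncated B (14912). It averaged 15656 ± 508 in control and 15739 ± 905 in truncated leaves (SD, n = 3; exact permutation test, two-sided, p = 0.9). No ID was listed at 0 in all libraries of one group and at 1 FPKM or more in all libraries of the other.

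**Figure D3:**
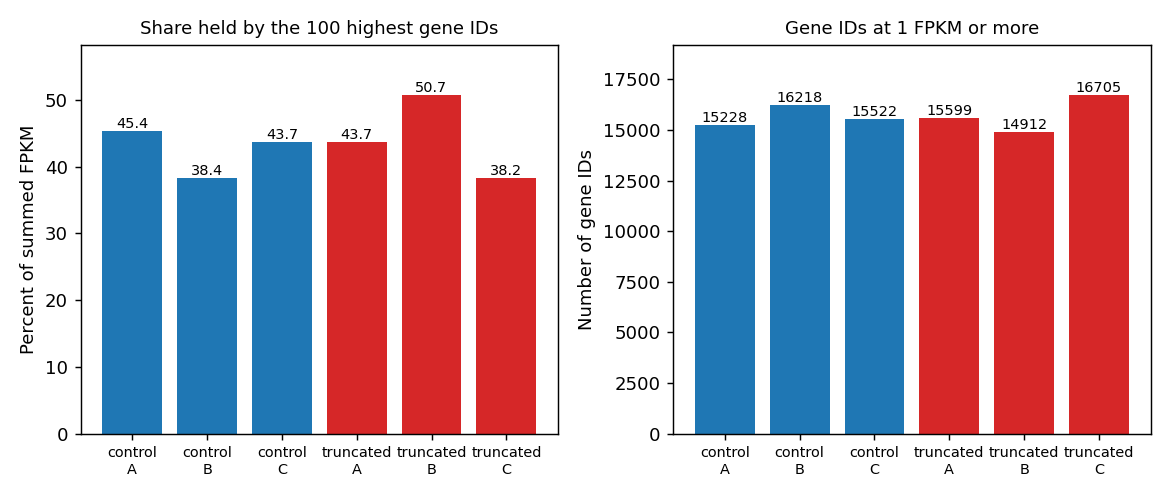
Percent of the summed FPKM held by the 100 highest gene IDs of each library (left) and number of IDs at 1 FPKM or more (right), for control (blue) and truncated (red) libraries A to C; both axes start at 0. Control B and truncated C have the lowest shares, 38.4% and 38.2%, and the most detected IDs, 16218 and 16705.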

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

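The count of 0 changed genes (limma, adjusted p under 0.05), in either direction and at 2-fold or more, stayed at 0 under the other pseudocounts, filters, scalings, variance models and threshold, without each library in turn, with the residual component as a covariate and without control B and truncated C together. The smallest adjusted p ranged from 0.0996 with the residual component to 0.992 without control A. Library quality weights, added after seeing the data, were the exception, with 1853 genes, 1098 higher and 755 lower, and 261 changed at least 2-fold. Their estimation stopped before converging, gave truncated A a weight of 45.0 and the other libraries at most 2.02, and called up to 4056 genes for other splits of the same libraries. The 1103 genes at an unadjusted p under 0.05 became 1663 with no filter (of 26044 tested) and 652 with a filter of 5 FPKM (of 9610 tested). They became 2878 with the residual component, a covariate that raised this count in all 10 splits of the libraries into 3 and 3. They became 4708 with the quality weights, for which the cause was not tested. They became 1336 without control B and truncated C together, and leaving out 1 library gave 659 (without control A) to 1639 (without truncated C). With the letter as a replicate block, 0 genes passed and 694 were at the unadjusted level. The labels do not say whether the letters pair the libraries. Control A, B and C did not each correlate best with the truncated library of the same letter. This cannot exclude a pairing, since control B and truncated C share a large deviation. Of the genes at the unadjusted level, 62.6% were higher in truncated leaves, which was 58.1% to 63.9% under the other scalings, 53.0% without truncated A or without truncated C, 70.7% without control C and 45.4% with the residual component. The fold changes of the 4 named IDs kept their direction throughout. As these IDs were chosen for groups that do not overlap, most of the settings could not have reversed it. The 4 IDs passed the threshold only with the quality weights, and Gb_23977 was not tested with the filter of 5 FPKM. Gb_23977 also had the widest range, a log2 fold change of 3.01 with a pseudocount of 0.1. Genes listed at 0 in one group numbered 86 when 0.1 FPKM sufficed in the other, and 1 to 5 without 1 library. The differences in detected genes and in the share of the 100 highest genes moved by less than 1 SD, though both changed sign without some libraries. The gene list alternatives and the count-based fits could not be run without gene names and counts.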

Other observations

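The tests of consecutive IDs by shuffling, of depth, of a uniform shift, of exchanged labels, of the treatment on the first component and of the splits were chosen only after the results they bear on had been seen. Gene IDs with consecutive numbers had more similar fold changes than IDs further apart in the numbering. Across 6928 pairs of consecutive Gb IDs, the log2 fold changes between truncated and control leaves correlated at r = 0.15 and rho = 0.10 across genes, which are not independent replicates (permutation test over 100000 shuffles of the IDs, one-sided, p = 1e-05 for both, the smallest the shuffles can give). The correlation was 0.095 at a distance of 2 in the numbering, 0.066 at 3, 0.0079 at 5 and 0.016 at 10. In 78 consecutive pairs both IDs were at an unadjusted p under 0.05, against a mean of 32.5 and at most 51 in 1000 shuffles. Of these pairs 66 had fold changes of the same direction, against a mean of 17.4 and at most 32 in the shuffles.

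The pattern of consecutive IDs is a hypothesis about clusters of related or co-expressed genes, since positions of the IDs are not used here. Copies with identical values do not account for the correlation, as leaving out every ID whose 6 values equal another's left r at 0.149 over 6839 pairs. The counts of pairs at the unadjusted level were not repeated without such copies. Whether the pattern is tied to the treatment cannot be told apart from a coupling present in any comparison of these libraries. The real split had the second highest r of 10, with 0.155 for control A, control B and truncated A against the rest and 0.078 to 0.127 for the other 8. Deviations of single libraries within groups correlated at 0.087 on average, lower than the fold changes. That lower value was set beforehand as evidence for a tie to treatment, but the prediction did not allow for fold changes averaging 3 libraries per group, which the splits do equally, and 10 splits are too few to decide. Reads shared between near-identical copies, gene models split in 2 and joint regulation remain open and untested.

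The largest component of variation did not follow the treatment. Control B and truncated C deviated from their group means in the same genes (r = 0.68 across genes). The first component set them apart from the other 4 libraries, of which truncated B lay furthest from them. Depth is argued against, since control B was at 0.94 of the depth of control A, within the range of the other 4 libraries (0.933 to 1.01). Only truncated B was lower in depth than control B, however, and truncated C was the deepest at 1.09. Sampling noise of weak genes is excluded as the whole cause, since r was 0.729 among the 1824 IDs of at least 50 FPKM. A uniform shift from a few abundant genes is excluded as the whole cause, since control A and control B were still at least 2-fold apart in 1377 IDs with the 100 highest IDs left out and median-of-ratios scaling, against 272 for control A and control C. A test set beforehand, the same r after that scaling, gave 0.687, past the bound of 0.4 set against a few abundant genes taking a different share of the fragments. It is not used as evidence, because a uniform shift would hardly alter r and the scaling moved it little from 0.68, so the exclusion rests on the later count.

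Exchanging the labels of control B and truncated C gave 213 genes at an unadjusted p under 0.05, fewer than the 1103 of the labels as given. This does not decide whether these libraries were swapped, because the count does not track the labels. Exchanging control B and truncated B instead gave 2271, more than the labels as given. The truncation treatment is not what the first component follows, as the truncated score was the higher in 3 of the 9 pairs of a truncated and a control library. Differences between trees, leaf age or position, harvest, RNA quality or library preparation remain open, since the labels give none of them and none of them was tested.

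The same structure limits what the comparison of treatments can show. Of the 10 splits of the 6 libraries into 3 and 3, 4 gave at least as many genes at an unadjusted p under 0.05 as the real one, with 1103 in the real split and at most 2271 in another. The splits with more genes all placed control B and truncated C on the same side and truncated B on the other. For non-overlapping groups, 4 of the 10 splits likewise gave at least the 2263 IDs of the real one, and at most 3124. For genes at an adjusted p under 0.05 in the fit without a covariate, and for those changed at least 2-fold, all 10 splits gave 0, so that the real value and the highest other were both 0. With the residual component as a covariate the real split still gave 0, but 4 other splits gave 465 to 735 genes. At an unadjusted p under 0.05, 5 of the 10 had at least the 2878 genes of the real one. This covariate, made from the same data, is by construction uncorrelated with the groups, so adding it cannot alter any fold change. That the median log2 fold change stayed at -0.0517 and those of the 4 named IDs were unchanged is therefore no sign of stability. The covariate raised the unadjusted count in all 10 splits, from 1103 to 2878 in the real one and from 77 to 465 in the lowest. The rise to 2878 therefore cannot be read as an effect of the treatment. With 10 splits no share under 0.05 can be reached.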
